A study of Mus musculus with 2 samples.

How the data were processed

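RNA sequencing compared 46C mouse embryonic stem cells that overexpressed either the Flag tag alone or Flag-tagged Prdm14. Per the labels' protocols, total RNA was taken from the cultures with Trizol, 1 ug went into each library, and libraries were made by the sequencing company's standard protocol and read on an MGI2000 instrument. The labels list 1 sample per condition, so the comparison had 1 library against 1 library as labelled. The title and sample labels name Prdm14, while the design text of the series names gadd45g as the tagged gene. The sample labels were used for grouping, and both genes' values open the report.

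The deposited file is a single table of 886 genes with an Ensembl gene ID, a mean TPM for each condition, a log2 fold change, a p-value, a q-value and a direction. Per the submitters' processing notes, the genome build was mm10 and Bowtie 0.12.2 was used; the program that estimated TPM and the test behind the p-values are not given in the sources used here. TPM, which scales reads by transcript length and by library to a fixed total, was computed by the authors and deposited as a mean, with no value per replicate. The number of values behind each mean is not given. Of the 1772 deposited TPM values, 872 (49.2%) carry 7 decimals, and the last decimal is a 5 in all 872, which is the form a mean of 2 values with 6 decimals takes. No SD could be computed, and the values are given as the authors' means.

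The log2 fold change deposited by the authors equals the log2 ratio of the Prdm14 mean to the Flag mean to within 4.09e-11, and its sign matches the deposited direction in all 886 genes. The table holds selected genes. The smallest absolute log2 fold change in the authors' deposited table is 1.00, the smallest value of the larger of both means is 5.01 TPM, and the largest q-value is 0.0427. The q-values in the authors' deposited table have the form of a Benjamini-Hochberg adjustment over 20309 genes: the rank this implies is a whole number to within 0.01 in 830 of the 886 genes. The largest implied rank is 4179, so the genes listed are a part of those at or below that q-value. Genes outside the table have no value here, and a gene's absence from it was not read as a lack of change. Values of 0.0001 TPM are the floor of the table (5 genes in the Prdm14 column and 1 in the Flag column). For these genes no fold is given.

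TPM values carry no read number, so the depth of the libraries is unknown and no counting interval could be given. The listed genes sum to 2.84% of the TPM total in the Flag column and 2.40% in the Prdm14 column.

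All 886 IDs matched a symbol and a gene of the GENCODE M21 annotation, whose build is the same as the one in the processing notes. Coordinates are 1-based on mm10 from that annotation. Folds in the text are ratios of the authors' means. Before the data were examined, 27 gene lists and 8 name-defined families were written down, along with the alternatives and the rule for naming genes. The rule takes Prdm14 and Gadd45g, the 10 genes with the largest log2 fold change in each direction among genes that are not predicted models or clone names and have a mean of at least 1 TPM over both conditions, and up to 4 members of each list with the largest absolute log2 fold change (all members where 5 or fewer are listed). Of the list members, 7 matched no symbol of the annotation. Some genes that the rule takes are not reported here. Other genes are said to be chosen after their values were seen.

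For each list with at least 5 listed members, the median log2 fold change was placed among the medians of 10000 random lists of the same size, drawn from the listed genes and matched on deciles of mean TPM. This percentile describes the deposited values and is not a test of the conditions, since genes are not replicates. On simulated data with 886 genes, 2% of 100 unrelated lists of 14 genes fell above the 97.5th percentile and 3% below the 2.5th, and 42% of 100 lists drawn mostly from higher genes fell above the 97.5th, so the percentile misses many such lists. The simulation shuffled the fold changes across genes, so it does not check the matching on mean TPM. Lists of other sizes were not simulated. Alternatives changed the fold and q thresholds, the TPM minimum, the pseudocount, the matching of random lists and the genes kept. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.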

Results

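The data describe gene expression in 46C cells, a mouse embryonic stem cell line with a green fluorescent protein reporter at Sox1, grown in serum with the cytokine LIF. The control cells overexpressed the Flag tag alone and the others Flag-tagged Prdm14, with 1 sample per condition in the labels. Values are the authors' mean TPM per condition for 886 genes that the authors listed as different, and their read depth is unknown. Every TPM value is from the authors' deposited table, and folds are ratios of its means. The differences have no replicate check here. "Higher" and "lower" refer to the Prdm14 cells relative to the Flag cells.

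Prdm14, a PR-domain DNA-binding regulator of pluripotency and of the germline, had the largest fold increase among genes that are not predicted models. Prdm14 (ENSMUSG00000042414, chromosome 1, 13113457 to 13127163, minus strand) went from 3.296 to 399 TPM, 121-fold higher in the authors' deposited table. The table does not separate transcripts of the introduced gene from those of the resident gene. Gadd45g (ENSMUSG00000021453, chromosome 13, 51846678 to 51848468, plus strand), a growth arrest and DNA damage gene that the design text of the series names in place of Prdm14, went from 21.6 to 3.57 TPM, 6.03-fold lower. The values therefore go with the sample labels and not with that text.

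The comparison asks which genes differ in expression when Prdm14 is overexpressed, the question in the series title. Of the 886 listed genes, 468 were higher and 418 lower in the authors' deposited table. The median fold was 2.56 among higher genes and 3.03 among lower genes. Large differences were mostly decreases: 145 lower and 77 higher genes differed at least 4-fold, and 67 lower and 13 higher genes at least 8-fold. Folds of genes with a low mean in 1 condition depend on how low values are treated: adding a pseudocount of 1 TPM reduced the fold over 1.5 times for 28 of 89 named genes off the floor, all 28 with a lower mean under 2 TPM. Members of gene lists that are outside the table have no value here.

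Genes of naive pluripotency were higher together. This list, the transcription factors and markers of the ground state of embryonic stem cells, had 14 of its 26 members among the listed genes, all of them higher. Tbx3 went from 10.5 to 62.6 TPM, 5.98-fold higher, Gbx2 from 5.77 to 33.03 TPM, 5.72-fold higher, Tfcp2l1 from 18.4 to 72.6 TPM, 3.94-fold higher, and Klf4 from 15.8 to 56.1 TPM, 3.56-fold higher. Nanog (117 to 344 TPM, 2.94-fold higher), Esrrb (84.8 to 229 TPM, 2.695-fold higher) and Zfp42 (232 to 649 TPM, 2.802-fold higher) are further members, chosen after their values were seen. In the authors' deposited table the list's median log2 fold change was 1.46, at percentile 99.90 of random lists matched on expression, and 1 of the 10000 random lists was entirely higher. Zfp42 lies on chromosome 8, where most listed genes were higher. Jam2, a surface protein on the list, and Tet2, an enzyme that oxidises 5-methylcytosine, were also higher, at 2.12-fold and 2.22-fold; Jam2 was chosen after its values were seen.

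Genes of the formative and primed states, which mark the cells of the epiblast around and after implantation, were lower together. Of the 23 list members, 15 were listed, all of them lower. Fgf5, a marker of the primed epiblast, went from 38.1 to 1.09 TPM, 34.9-fold lower (18.7-fold with a pseudocount of 1). Pou3f1, a POU-domain factor of the epiblast, went from 149.8 to 4.89 TPM, 30.6-fold lower, and Car4, a carbonic anhydrase, from 75.5 to 4.88 TPM, 15.5-fold lower. Dnmt3b, a de novo DNA methyltransferase, went from 1032 to 78.7 TPM, 13.1-fold lower. Otx2, an epiblast transcription factor chosen after its values were seen, went from 293 to 113 TPM, 2.58-fold lower. The median log2 fold change in the authors' deposited table was -1.83, at percentile 0.02, and 0 of the 10000 random lists were entirely lower.

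**Figure D1:**
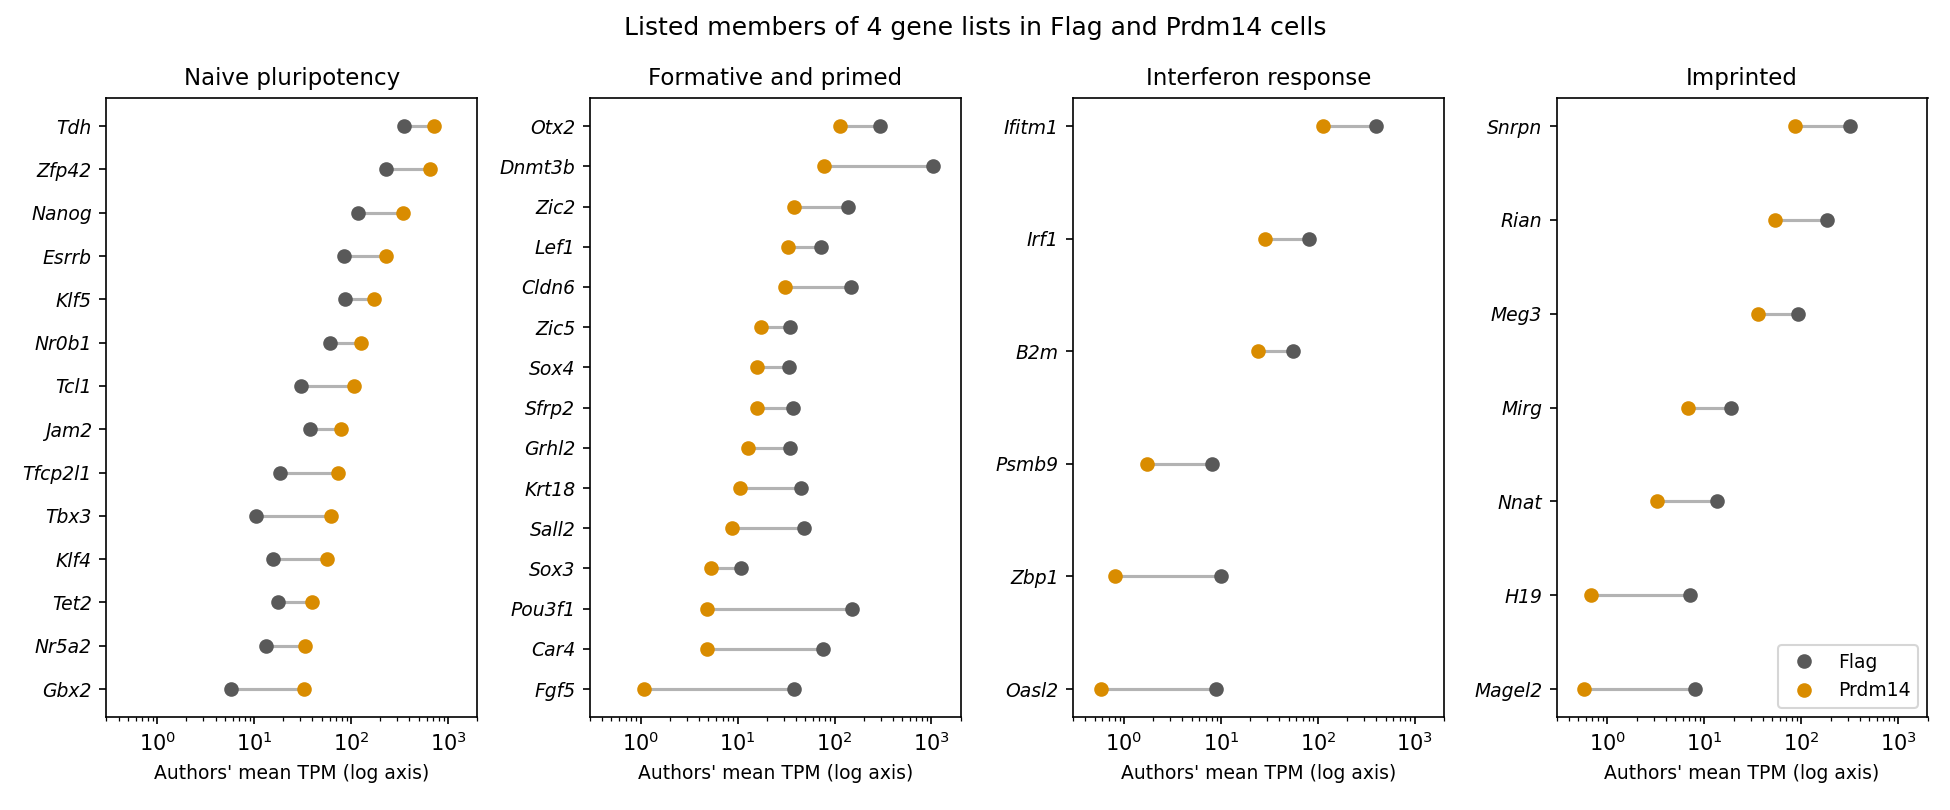
Authors' mean TPM on a log axis in Flag (grey) and Prdm14 (orange) cells for each listed member of 4 gene lists, with a line joining the 2 values of a gene. All 14 naive members lie further right in Prdm14 cells and all 15 formative members further left, and the listed interferon and imprinted genes also lie further left (Psmb8, at the floor of the table in Prdm14 cells, is not drawn).

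DNA methylation genes were among those with high levels that differed. Besides Dnmt3b, its catalytically inactive partner Dnmt3l went from 482 to 168 TPM, 2.86-fold lower. Dnmt3l was also the single listed member of the 10-gene core pluripotency list. Of the 18 genes of the DNA methylation list, 4 were listed: Dnmt3b, Dnmt3l and Gadd45g were lower, and Tet2 went from 17.7 to 39.2 TPM, 2.22-fold higher. Dnmt3c, a further de novo methyltransferase gene chosen after its values were seen, went from 22.5 to 1.14 TPM, 19.7-fold lower. The list of 18 Prdm14 partner and Polycomb genes had no member among the listed genes.

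Of 14 listed members of the 52-gene germ cell list, 10 were higher and 4 lower, with the median at percentile 90.4. Of the 10000 random lists, 958 had at least as many higher members. Among members with an absolute log2 fold change of at least 2, 1 was higher and the median was -3.24, which is the value of Xlr3b. Nanos3, an RNA-binding protein needed by primordial germ cells, went from 1.08 to 6.49 TPM, 6.03-fold higher, and the receptor Kit from 12.8 to 48.1 TPM, 3.76-fold higher. Dazl, a germ cell RNA-binding protein chosen after its values were seen, went from 4.11 to 14.5 TPM, 3.52-fold higher. Zp3, an egg coat protein, was at 10.7 TPM in Flag cells and at the floor in Prdm14 cells, and Xlr3b went from 5.504 to 0.583 TPM, 9.44-fold lower. Nanos3 overlaps microRNA genes on its own strand, and Xlr3b belongs to a family of close copies, so both values are uncertain. Nanos3 and Tex15, another higher member, lie on chromosome 8. Xlr3b and Xlr3a, another lower member, lie on chromosome X, where most listed genes were lower.

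Signalling genes went both ways. Of 7 listed genes of the 30-gene TGF-beta, Nodal and BMP list, 4 were higher and 3 lower, with the median at percentile 67.3. Among those with an absolute log2 fold change of at least 2, 2 were higher and the median was -2.23. The Nodal target Lefty1 went from 137 to 18.9 TPM, 7.23-fold lower, while the secreted matrix protein gene Tgfbi went from 1.97 to 23.05 TPM, 11.7-fold higher, and the inhibin subunit gene Inhbb from 1.66 to 8.63 TPM, 5.19-fold higher. Of 7 listed genes of the 34-gene FGF and ERK list, 4 were higher and 3 lower, at percentile 68.02. Spred1, an inhibitor of ERK signalling, was 2.46-fold higher. Etv4, Spry4 and Shisa2, chosen after their values were seen, were 2.31-fold, 2.32-fold and 2.15-fold higher. The lower members were Fgf5, Fgfr2 and Spred3. Only Fgf5 and Fgfr2 had an absolute log2 fold change of at least 2, and their median was -3.64. The 19-gene LIF and STAT3 list had 5 listed members, of which Gbx2, Tfcp2l1, Klf4 and Pim1 were higher and Socs3, a feedback inhibitor of this pathway, went from 7.89 to 2.58 TPM, 3.06-fold lower. Its median was at percentile 99.35, and 3 of its higher members are also on the naive list. The one listed gene of the 24-gene Wnt list was Lef1, 2.18-fold lower.

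Interferon response genes were lower. All 7 listed members of the 35-gene list were lower, with a median log2 fold change of -2.24 in the authors' deposited table, at percentile 0.29. Of the 10000 random lists, 80 were entirely lower. Psmb8 and Psmb9 lie close together on chromosome 17, while the random lists treat them as separate. Psmb8, an immunoproteasome subunit, was at 11.8 TPM in Flag cells and at the floor in Prdm14 cells. Oasl2 went from 8.897 to 0.586 TPM, 15.2-fold lower, Zbp1, a nucleic acid sensor, from 10.1 to 0.813 TPM, 12.4-fold lower, and Psmb9 from 8.105 to 1.72 TPM, 4.72-fold lower. Among the 10 genes with the largest decreases were Gbp2b and Gbp2, interferon-inducible guanylate-binding proteins, at 10.5 to 0.0453 TPM and 18.9 to 0.119 TPM; these are close copies of each other and their values are uncertain.

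Imprinted genes, expressed from the allele of 1 parent, were also lower. All 7 listed members of the 43-gene list were lower, with a median log2 fold change of -1.88 in the authors' deposited table, at percentile 2.52, and 61 random lists were entirely lower. Magel2 went from 7.98 to 0.572 TPM, 13.95-fold lower (5.71-fold with a pseudocount of 1), H19 from 7.03 to 0.679 TPM, 10.4-fold lower, Nnat from 13.6 to 3.27 TPM, 4.15-fold lower, and Snrpn from 317 to 86.4 TPM, 3.67-fold lower. The 7 are not independent genes: Meg3, Rian and Mirg are neighbours in 1 imprinted cluster, and Magel2 and Snrpn lie in another on chromosome 7, while the random lists treat them as separate. Snhg14, the long RNA that runs on from Snrpn, was at 17.9 TPM in Flag cells and at the floor in Prdm14 cells.

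Cell adhesion and matrix genes were mostly lower, at 9 of 12 listed members of 47, with the median at percentile 0.86. Among the lower ones, Cldn6 is also on the formative list, Lama1 and Col4a2 on the primitive endoderm list, and Cdh2 on the neuroectoderm list. The tight junction genes Cldn7 (39.9 to 5.67 TPM, 7.04-fold lower) and Cldn6 (147 to 30.6 TPM, 4.801-fold lower) and Cldn4 (45.9 to 11.7 TPM, 3.93-fold lower) were lower. Zeb1, a transcriptional repressor of epithelial genes, went from 2.102 to 11.9 TPM, 5.65-fold higher.

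Among markers of other lineages, the primitive endoderm genes were lower and the other lists went both ways. All 4 listed genes of the 38-gene primitive endoderm list were lower: Cubn went from 7.36 to 0.134 TPM, 54.8-fold lower (7.37-fold with a pseudocount of 1), and Dab2 was 11.7-fold, Col4a2 3.16-fold and Lama1 3.03-fold lower. The 55-gene neuroectoderm list had 7 higher and 5 lower members, led by Gfra1 (5.63 to 0.398 TPM, 14.1-fold lower, or 4.74-fold with a pseudocount of 1) and Sox21 (1.04 to 8.34 TPM, 8.02-fold higher). The 36-gene trophoblast list had 3 higher and 4 lower members, including the galectin gene Lgals3 (30.3 to 132 TPM, 4.36-fold higher) and Krt18 (45.4 to 10.6 TPM, 4.298-fold lower), which is on the formative list as well. The 46-gene fibroblast and feeder list had 3 higher and 4 lower members, including the smooth muscle genes Myl9 (11.6 to 1.74 TPM, 6.62-fold lower) and Tagln (5.91 to 1.23 TPM, 4.79-fold lower), and Ccnd2 (9.92 to 30.6 TPM, 3.09-fold higher). Of the 44-gene primitive streak and mesoderm list, Bmp4 was 2.54-fold higher and Snai1 4.45-fold lower. The 23-gene blood and endothelium list had no listed member. The percentiles were 76.9 for neuroectoderm, 32.6 for trophoblast and 10.5 for fibroblasts.

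**Figure D2:**
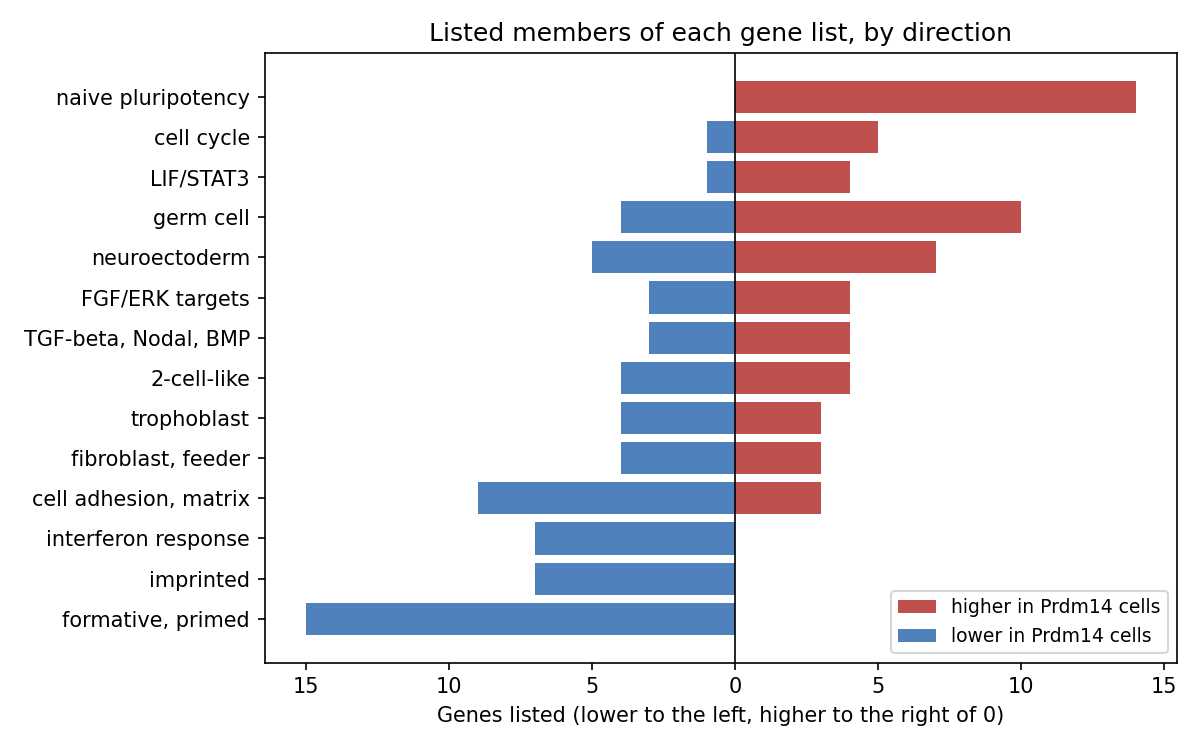
Number of listed genes of each gene list with at least 5 listed members, with lower genes drawn to the left of 0 and higher genes to the right. The naive list has 14 higher and 0 lower genes and the formative list 0 higher and 15 lower.

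Of 8 listed members of the 42-gene list of the 2-cell-like state, 4 were higher and 4 lower: Gm5662 went from 0.974 to 6.99 TPM, 7.17-fold higher, while the Dux-related genes Duxbl1, Duxbl2 and Duxbl3 were 7.73-fold, 11.2-fold and 10.8-fold lower, as was Snai1. Zscan4c, Zscan4e and Zscan4f, chosen after their values were seen, were 3.64-fold, 3.27-fold and 3.54-fold higher. The copies within each family share sequence, so their single values are uncertain. The list's median was at percentile 62.6 of matched and 33.4 of unmatched random lists.

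Cell cycle genes were higher in 5 of 6 listed cases out of 36, with the median at percentile 94.5. Cdkn2a, an inhibitor of cell division, went from 6.14 to 27.98 TPM, 4.56-fold higher, Rbl2, a retinoblastoma relative on chromosome 8, from 4.84 to 14.7 TPM, 3.04-fold higher, and Mycn from 250.2 to 104 TPM, 2.41-fold lower. The other higher members were Ccnd2 (3.09-fold), Ccnd3 (2.18-fold) and Cdk6 (2.21-fold). Ccnd3 and Cdk6 were chosen after their values were seen. The p53 target list had 3 of 24 members listed, all higher: Gdf15 was 2.65-fold, Pmaip1 2.26-fold and Perp 2.25-fold higher. Gdf15 also lies on chromosome 8. Of the 32-gene ATF4 stress list, Asns was 2.24-fold higher, and Chac1, Cebpb and Stc2 were 2.36-fold, 2.29-fold and 2.21-fold lower. The glycolysis and hypoxia list (38 genes) had Ddit4, the sterol synthesis list (27 genes) Fads2 and the dissociation response list (20 genes) Jun as single listed genes, which were 2.24-fold, 2.37-fold and 2.898-fold lower. No gene of the 23-gene heat shock list, and no ribosomal protein, Hox or Rhox gene, was listed.

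The remaining largest increases were in Pagr1a (0.428 to 12.1 TPM, 28.3-fold higher), Tppp3 (6.06 to 74.1 TPM, 12.2-fold higher), Lrrn2 (0.947 to 8.85 TPM, 9.35-fold higher), Pou4f2 (1.44 to 13.4 TPM, 9.30-fold higher), Pdyn (1.75 to 14.6 TPM, 8.38-fold higher), H60b (0.837 to 6.56 TPM, 7.83-fold higher) and Zfp800 (0.722 to 5.38 TPM, 7.45-fold higher). Pagr1a overlaps the near-identical Pagr1b on its strand, so its value is uncertain, and its fold was 9.18 with a pseudocount of 1. Tppp3 and Pou4f2 lie on chromosome 8. Further large decreases were in Foxi3 (31.8 to 0.4704 TPM, 67.6-fold lower) and Hs6st2 (5.17 to 0.0836 TPM, 61.9-fold lower), the latter on chromosome X. With a pseudocount of 1 these folds were 22.3 and 5.70. Glod5, also on chromosome X, and Lypd2, at 8.65 and 5.52 TPM in Flag cells, were at the floor in Prdm14 cells. The mitochondrial gene mt-Atp6 went from 6604 to 1406 TPM, 4.698-fold lower; it overlaps its neighbours mt-Atp8 and mt-Co3, and no other mitochondrially encoded gene was listed. All 4 listed histone genes were higher, H2afy2 by 3.69-fold and Hist2h3c1 by 3.56-fold. Of 2 listed host genes of small RNAs, Mir124a-1hg was 5.43-fold higher and Mir670hg 7.58-fold lower. Prdm14 was the single listed gene of the Prdm family. Predicted genes numbered 57, with 42 higher and 15 lower.

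By chromosome, the direction of the listed genes was uneven. On chromosome 8, 51 listed genes were higher and 13 lower, so 79.7% were higher against 52.8% over the table. On chromosome X, 6 were higher and 35 lower. Among 10000 expression-matched draws of as many listed genes, 0 reached the number of higher genes on chromosome 8 and 0 the number of lower genes on chromosome X. By the number of draws as uneven in the same direction, chromosomes 7 (24 higher, 46 lower, 13 draws), 11 (24 higher, 42 lower, 50 draws) and 9 (31 higher, 14 lower, 118 draws) were next. Without chromosomes 8 and X, an alternative chosen after seeing the data, 411 genes were higher and 370 lower.

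**Figure D3:**
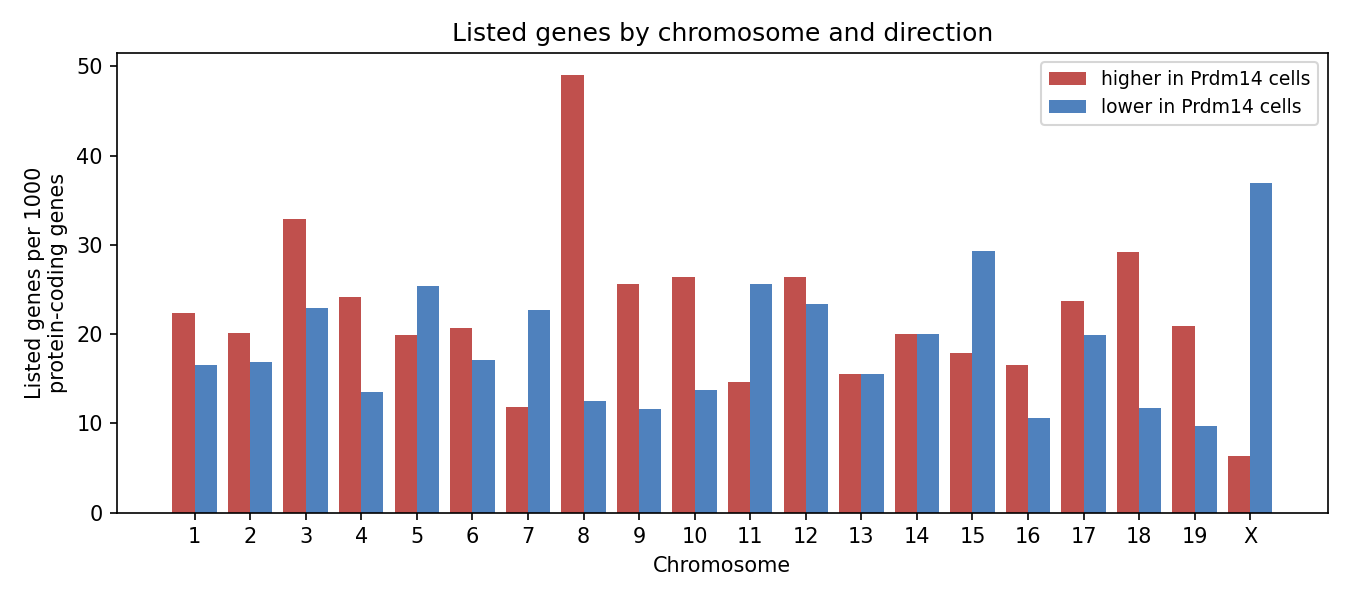
Listed genes per 1000 annotated protein-coding genes on each chromosome, with genes higher in Prdm14 cells in red and lower genes in blue. Chromosome 8 has 49.0 higher genes per 1000 and chromosome X has 36.9 lower genes per 1000.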

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

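Alternatives that left out chromosomes 8 and X, overlapping genes or floor genes were chosen after seeing the data. The counts of 468 higher and 418 lower genes stayed within 1.5 times under both q thresholds, both TPM minimums, without predicted genes and without chromosomes 8 and X or overlapping genes. At an absolute log2 fold change of at least 2 they fell to 77 and 145, and at 3 to 13 and 67, as a stricter threshold must; the share of higher genes went from 52.8% to 34.7% and 16.3%. The log2 fold change of Prdm14 was 6.92 in the authors' deposited table, 6.54 with a pseudocount of 1 and 6.88 with 0.1. With a pseudocount of 1, the list medians were 1.45 for naive, -1.81 for formative, -1.80 for interferon and -1.78 for imprinted genes. Among members with an absolute log2 fold change of at least 2 they were 2.55, -3.71, -3.78 and -3.37 in that order. All listed members of each of these lists go in 1 direction, so this threshold was bound to move the medians outward. The naive value rests on 2 genes. Without chromosomes 8 and X the naive median was 1.49 and the formative median -1.97, and without floor genes the interferon median was -2.03. Medians of 4 lists with members in both directions changed sign when only members of at least 2 on the log2 scale were kept: FGF and ERK (-3.64), TGF-beta (-2.23), germ cell (-3.24) and neuroectoderm (-0.41). The germ cell value is that of Xlr3b alone, a gene whose value is uncertain. The imprinted percentile was 2.52 with matched and 2.32 with unmatched random lists, on either side of 2.5. A pseudocount cannot change the sign of a single gene's fold change, but it reduced the fold over 1.5 times for 28 of 89 named genes off the floor at 1 and for 5 at 0.1; the log2 fold change of Cubn went from -5.78 to -2.88 and that of Hs6st2 from -5.95 to -2.51 at 1. A minimum of 1 TPM removed no gene. No paired analysis was possible because the table holds 1 value per condition. Leaving out a replicate was not possible for the same reason. Read depth is unknown, so its limit on low genes could not be measured.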

Other observations

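Further genes that work in antigen presentation or are induced by interferon were picked after their values were seen, and no enrichment was tested. H2-Q2, an MHC class I gene, went from 6.36 to 0.404 TPM, 15.8-fold lower, and the peptide-processing genes Erap1, Tap2 and Psme2 from 9.34 to 0.318 TPM, 29.4-fold lower, from 6.41 to 0.684 TPM, 9.37-fold lower, and from 165 to 49.96 TPM, 3.31-fold lower. Irgm1, an interferon-inducible GTPase gene, went from 22.2 to 4.596 TPM, 4.84-fold lower, and Parp9 and Parp12 from 22.1 to 6.02 TPM, 3.68-fold lower, and from 44.5 to 12.4 TPM, 3.599-fold lower. Of 10 listed glutathione transferase genes, also picked after their values were seen, 8 were lower, including Gstm1 (94.98 to 29.9 TPM, 3.18-fold lower) and Gstt2 (48.2 to 10.3 TPM, 4.68-fold lower), while Gsta3 and Gstp3 were 2.503-fold and 3.71-fold higher. Close copies can share reads, so values of related genes are not independent of each other.

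Single genes with large differences, likewise picked after their values were seen, included Lefty2 (109.7 to 23.5 TPM, 4.68-fold lower), Foxh1 (95.96 to 20.7 TPM, 4.63-fold lower) and the X-linked kinase gene Pim2 (430.4 to 20.3 TPM, 21.2-fold lower). The fixed TGF-beta, Nodal and BMP list, which is related to Lefty2, had 4 higher and 3 lower members. The predicted gene Gm45717 went from 1.08 to 313 TPM and Gm11960 from 0.575 to 41.03 TPM. Gm45717 overlaps Ifitm2 and Ifitm5 on its strand, so its reads cannot be assigned with certainty.

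The tests of technical explanations given here were all chosen after the results were seen. The first pattern is that the 14 listed naive genes were higher and the 15 listed formative genes lower. Fewer cells of all differentiated lineages would lower their markers alike, but 54.8% of 31 listed lineage markers (17) were lower and 14 were higher. Over the whole table, 52.8% of genes were higher. The 4 primitive endoderm genes among the markers were all lower, so fewer cells of that lineage remain open. Genes of the pluripotency lists, formative ones included, were left out of the markers. A smaller share of formative cells in the culture was therefore not tested and stays open too. Means over a culture do not separate it from lower expression per cell. A gene length bias as the whole cause would part the lists by length, but the naive gene was longer in 58.6% of naive and formative pairs, and the shortest, middle and longest tertiles held 5 of 10, 2 of 9 and 7 of 10 naive genes. An effect of Prdm14 on these genes was not tested beyond the comparison itself, since no values per replicate were used here.

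The second pattern is the excess of higher genes on chromosome 8. Chance drawing of genes gave as many in 0 of 10000 draws, although neighbouring genes are not independent and 20 chromosomes were looked at. A higher copy number of chromosome 8 in the Prdm14 cells may account for part of it, since higher genes per protein-coding gene were at least 2.27 times those of the other autosomes in each of 3 equal parts of the chromosome. If an added copy acted mostly on genes near the 2-fold threshold, the excess would narrow among larger changes. The share of higher genes exceeded that of the other chromosomes by 26.6 percentage points under 4-fold and by 26.5 among larger changes (6 of 10 genes), which is no narrowing. An added copy would also carry some genes past 4-fold, and the larger changes are few, so this comparison cannot decide. Copy number therefore stays open, as does an effect of Prdm14 on genes of this chromosome, which was not tested.

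The third pattern is the excess of lower genes on chromosome X, which 0 of 10000 chance draws reached. If a lower copy number of X mostly added lower genes near 2-fold, more of its lower genes would be under 4-fold. In fact 62.9% of the X-linked lower genes were under 4-fold against 65.5% elsewhere, a difference of -2.68 percentage points. A lower copy number would also carry some genes past 4-fold, so this share cannot decide. The share of lower genes on X exceeded that elsewhere by 42.1 percentage points under 4-fold (81.5% against 39.4%) and by 29.4 among larger changes (92.9%, or 13 of 14 genes, against 63.5%). With 63.5% already lower elsewhere, an excess of 42.1 points could not be reached among larger changes, so some narrowing was bound to occur. Neither comparison can decide, and genes below the 2-fold threshold have no value here, so the explanation stays open. The copy number of X was not measured here in either culture. A biological difference between the conditions was not tested for this pattern.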
